A study of Mus musculus with 8 samples.

How the data were processed

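Neural stem cells isolated from mouse embryos at embryonic day 13.5 were kept at 5% oxygen (called hypoxia here) or at 21% oxygen (normoxia) for at least 10 days, per the labels' protocols. RNA from 4 cultures of each kind, with an integrity number above 7 per the labels, was labelled with Cy3 and hybridised to 1-colour Agilent mouse expression arrays. All 8 arrays lay on 1 slide, so no slide or scan batch could be tested. Groups and replicate numbers came from the sample titles.

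The deposited intensity values were made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Per the file headers, the processed signal is the spot's intensity after background subtraction and detrending, with no scaling between arrays. The authors' deposited value table is on a log2 scale. Set against the scanner values, it equals the log2 processed signal minus each array's 75th percentile minus each probe's median over the 8 arrays, to within 0.01 for 99.72% to 99.76% of probes per array. The medians of its columns ran from -0.12 to 0.25. This table served as an alternative.

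The values analysed were log2 of the processed signal minus each array's 75th percentile over non-control spots. Control spots and spots marked as non-uniform or as population outliers were left out, and spots of 1 probe were averaged. A probe was kept when it was well above background on at least 3 of the 4 arrays of at least 1 group, which left 37669 of 55681 probes. The files used here carry accessions in place of gene symbols. Matched without version numbers to RefSeq genes of assembly GRCm38.p6, 27235 probes gained a symbol and 28446 did not, and the latter kept their accession. The array was designed on another build, so no coordinates are printed. The probe with the highest mean signal stood for each gene, which gave 26874 genes and transcripts, 16065 of them RefSeq genes. Among the 298 genes past the threshold in the paired fit that had more than 1 kept probe, 2 had probes with an unadjusted p under 0.05 in both directions.

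Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit set before the data were examined had 1 mean per group and no block, and is called the unpaired fit. A fit with the replicate number as a block, called the paired fit, was the alternative named beforehand. Each of the 4 experiments used different donors, per the series' design text, and both oxygen conditions ran side by side, per the labels' protocols. Deviations from the group means correlated across genes between same-numbered arrays at 0.76, 0.51, 0.38 and 0.66. Every array correlated best with its own number, though in replicate 3 the 0.38 stood against up to 0.31 with another number. The numbers were therefore taken to pair the samples, and values of the paired fit stand beside those of the unpaired fit.

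For 31 gene lists fixed before the data were examined, limma's camera compared each list of at least 5 tested genes with the other genes, in both directions, with a preset correlation of 0.01 and adjustment over the 30 lists tested. The test was repeated with the correlation estimated per list, with ranks and with fry. The list of calcineurin and NFAT components was chosen knowing that published work on these samples deals with it, so it is not independent evidence. Named genes followed a rule set before the data were examined: up to 15 per direction with the largest change among those past the threshold that moved the same way in all 4 pairs, filled from the paired fit, up to 4 members past the threshold per list or else the 2 with the smallest p, all members of the HIF system and calcineurin lists, and housekeeping and sex-linked genes as checks. Applying the first and the list parts of this rule to the paired fit as well was decided after the counts had been seen. Some genes that the rule names are not reported here.

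The procedure was tested on simulated arrays with the real probe means and spreads, independent genes and 200 changed genes in each of 3 simulations of the comparison over 26874 genes. The unpaired fit recovered 0% of genes changed 1.5-fold, 22.7% at 2-fold, 60% at 3-fold and 81.3% at 5-fold. The paired fit recovered 1.33%, 34.7%, 72% and 88%. Of 298 paired calls 4 were false, and of 246 unpaired calls none. Changed genes were drawn at random and given the same change in every pair. In the data the calls stood much further apart, at 24 unpaired and 1482 paired. The shares recovered need therefore not hold for the genes that changed here, above all in the unpaired fit.

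Alternatives covered the block, background correction, scaling, the filter on dim probes, the gene summary, spot flags, moderation, array weights and leaving out each array or pair. The files used here hold no mean spot signal, so background correction by normexp with an offset of 50 used the median spot signal. In the alternative with trend and robust moderation, the list test used the trend alone. The number of arrays limits the precision, and no saturated spot occurred.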

Results

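The study profiled gene expression in embryonic mouse neural stem cells kept at low oxygen, to find regulators through which oxygen acts on these cells. The data comprised 8 arrays, 4 of cells at 5% oxygen and 4 of cells at 21% oxygen, from 4 independent experiments on different donors. Same-numbered arrays were taken to come from the same experiment. Each array held 62976 spots. Between 64.4% and 73.9% of the non-control spots were well above background, and the 75th percentile of the signal ran from 1909 to 7352 intensity units. This percentile was lower on the hypoxia array in pairs 1 (1909 against 2990), 2 (4784 against 7299) and 4 (5438 against 7352). In pair 3 it was higher there (6781 against 5310). Values are log2 signal relative to that percentile, and fold changes are hypoxia over normoxia.

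Genes that rose at low oxygen in the unpaired fit included Prelid2, Slc2a3, Pfkp and the prolyl hydroxylase gene Egln3. In this fit, 24 of 26874 genes and transcripts passed the threshold, and all 24 rose by at least 2-fold. Prelid2 rose by 8.81-fold (log2 3.14, SE 0.43, adjusted p = 0.0385), from -0.66 ± 0.78 to 2.48 ± 0.68 (SD, n = 4 per group). Slc2a3, a glucose transporter, rose by 5.00-fold (adjusted p = 0.0385), and Pfkp, a phosphofructokinase of glycolysis, by 3.75-fold (adjusted p = 0.037). Rgs11, a regulator of G protein signalling, rose by 5.40-fold and Rab33a by 4.43-fold. The amino acid transporter gene Slc38a4 rose by 4.32-fold, the phosphodiesterase gene Pde4a by 2.95-fold and the cell adhesion gene Icam1 by 2.71-fold. Sgcd, Sh2d5, Bean1, Gng3, Tmem74b and Ccdc8 rose by between 3.09-fold and 4.40-fold, and Sgcd was well above background on 3 of the 4 normoxia arrays. With the pairs as a block, 1482 genes passed, of which 1134 rose and 348 fell, and 747 changed by at least 2-fold. All 24 genes of the unpaired fit were among them. Of the 1482, 1481 moved the same way in all 4 pairs, which passing the threshold with 4 pairs largely entails, so this is no further support. The unpaired count was 0 (limma, with 1317 to 2269 genes at an unadjusted p under 0.05) without normoxia replicate 1, 3 or 4, without hypoxia replicate 1, 2 or 3 and without any of the 4 pairs, and it was 58 without normoxia replicate 2 and 53 without hypoxia replicate 4. It was also 0 under quantile normalization, under median scaling and with no filter on dim probes, whereas the paired count was 712, 823, 389 and 1429 without pairs 1, 2, 3 and 4.

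Ndufa4l2, which encodes a mitochondrial protein, showed the largest increase of the paired fit, at 36.8-fold (log2 5.20, SE 0.51, paired adjusted p = 0.00211), with Car9, a carbonic anhydrase, at 19.1-fold (adjusted p = 0.00182) and Slc16a3, a lactate transporter, at 17.7-fold (adjusted p = 0.0213). None of these 3 passed in the unpaired fit (adjusted p = 0.0555, 0.093 and 0.185), in which the normoxia arrays spread by SDs of 1.88, 1.92 and 2.53. Ppp1r3g, Mgarp, Trpm2, Stac2, Chst5, Pdlim3 and Loxl2 rose by between 6.86-fold and 10.2-fold in the paired fit. Trpm2 was well above background on 1 of the 4 normoxia arrays and Chst5 on 3. Slc16a3 was at 12.1-fold without pair 1 (adjusted p = 0.053) and 28.2-fold without pair 3 (0.0808), where its call was lost, at 29.3-fold without pair 2 and at 9.68-fold without pair 4. Chst5 was at 3.66-fold without pair 4, and its call was lost without pair 1 (8.88-fold, adjusted p = 0.0613), 2 (11.3-fold, 0.0556) or 3 (7.47-fold, 0.204). Ndufa4l2 was at 58.2-fold without pair 2 and Loxl2 at 4.39-fold without pair 1, and the Loxl2 call was lost without pair 3 (7.85-fold, adjusted p = 0.0808).

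**Figure D1:**
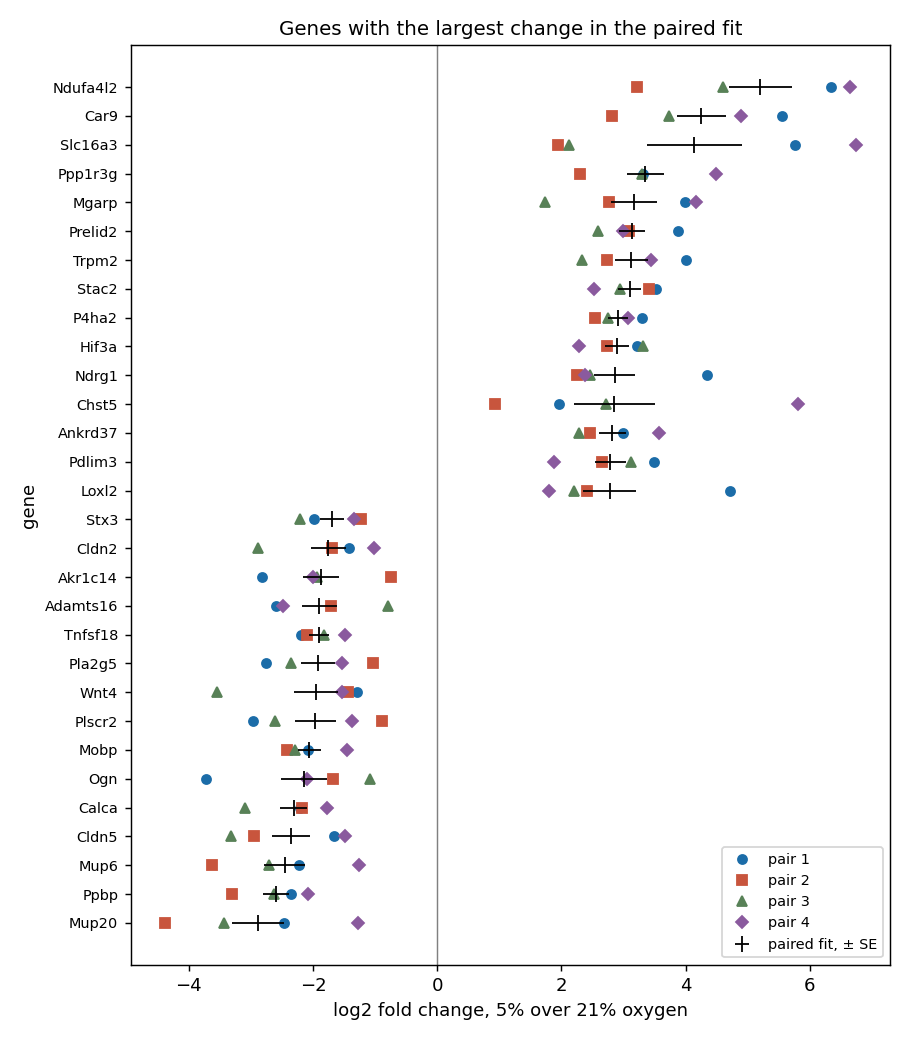
Log2 fold change of hypoxia over normoxia for the 15 genes with a RefSeq symbol that rose most and the 15 that fell most in the paired fit. Symbols are the 4 same-numbered pairs and black bars the paired estimate ± SE. By the naming rule only genes past the threshold that moved the same way in all 4 pairs could be shown. Their changes ran from 5.20 for Ndufa4l2 to -2.88 for Mup20.

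Of 41 known target genes of hypoxia-inducible factor (HIF) tested, 31 rose and none fell in the paired fit, against 1, Egln3, in the unpaired fit. Adjusted over the list alone, 36 rose in the paired and 31 in the unpaired fit. The median change was 1.03, and it lay between 0.99 and 1.29 in each pair. P4ha2, a collagen prolyl hydroxylase, rose by 7.54-fold, Ndrg1 by 7.25-fold and Ankrd37 by 7.07-fold in the paired fit. The list shifted up by camera in the unpaired fit (adjusted p = 1.99e-35, and adjusted p = 0.127 with an estimated correlation). No other split of the 8 arrays among 35 gave the list as small a p, the smallest other camera p being 2.98e-20. Only 8 of the splits part all 4 same-numbered pairs, too few for a share under 0.05.

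Among 12 components of the HIF system, 5 rose in the paired fit. Egln3, a prolyl hydroxylase that marks HIF for degradation, rose by 3.31-fold in both fits, and Egln1 by 1.93-fold in the paired fit. Hif3a rose by 7.41-fold, Epas1 by 2.49-fold and Vhl, which binds hydroxylated HIF, by 1.53-fold in the paired fit. The Vhl call was lost without any 1 of the 4 pairs (paired adjusted p from 0.0906 to 0.128). The Epas1 call was lost without pair 1, 2 or 3 (0.0788, 0.0981 and 0.148) and the Egln1 call without pair 3 (0.0507). Hif1a did not pass (log2 change -0.31, SE 0.17, paired adjusted p = 0.379), and on hypoxia replicate 1 it lay at 1.21 against 2.43 to 2.51 on the other hypoxia arrays, with normoxia replicate 1 at 2.04 the lowest of its group too. The changes of Arnt (0.11), Arnt2 (-0.51), Egln2 (-0.04), Hif1an (-0.32), Ep300 (-0.37) and Crebbp (0.01) did not pass either. Adjusted over the list alone, 5 rose in each fit and 1 fell in the paired fit. The list did not pass by camera in the unpaired fit (adjusted p = 0.083) and passed with a direction of up in 8 of 42 settings (smallest 0.0338). It passed by fry in 1 direction, which sets no list against other genes (adjusted p = 0.0425, and 0.00745 in the paired fit).

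Glycolysis and lactate genes were higher in all 23 members tested, with a median change of 0.51. In the paired fit 10 rose and none fell, in the unpaired fit Slc2a3 and Pfkp, and adjusted over the list alone 16 and 10. Pdk1, a kinase that restrains pyruvate entry into the citric acid cycle, rose by 6.44-fold and the enolase gene Eno2 by 5.57-fold in the paired fit. The list shifted up (camera adjusted p = 6.07e-15, and adjusted p = 0.261 with an estimated correlation), and no other split of the arrays gave as small a p. Genes of oxidative phosphorylation did not pass as a list by camera (adjusted p = 0.325, and 0.173 in the paired fit), but passed with ranks in the paired fit (0.0409) and with a direction of up without normoxia replicate 1 (0.00621) and in the leave-one-out with replicate block, without pair 3 (0.0153), and none of its 46 members passed. Its members with the smallest p were Cox8a (0.27) and Atp5b (0.25).

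Cholesterol synthesis genes were higher in 24 of 25 members, with a median change of 0.39. It was 0.05 in pair 3, where the median over all genes was -0.13. In the paired fit 3 rose, among them the mevalonate pathway enzymes Mvd and Pmvk by 1.75-fold and 1.59-fold. The Mvd and Pmvk calls were lost without any 1 of the 4 pairs (paired adjusted p from 0.0672 to 0.223). Adjusted over the list alone, 7 rose in the paired and 1 in the unpaired fit. The list shifted up (camera adjusted p = 2.02e-08, and adjusted p = 0.366 with an estimated correlation), and 2 of the 35 splits, the real one included, gave as small a p.

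The genes with a RefSeq symbol that fell furthest did so in the paired fit. Cldn5, a tight junction gene of endothelium, fell by 2.36 on the log2 scale (5.12-fold, SE 0.31, paired adjusted p = 0.0056, and 0.0519 without pair 3) and Cldn2 by 1.75. Calca, which encodes calcitonin and its related peptide, fell by 2.31, from 2.24 ± 0.32 to -0.07 ± 0.81 (SD, n = 4). Wnt4 fell by 1.95, the secreted proteoglycan gene Ogn by 2.15 and the myelin gene Mobp by 2.06. Ppbp fell by 2.59, Tnfsf18 by 1.90, Pla2g5 by 1.91, Adamts16 by 1.90, Akr1c14 by 1.87, Plscr2 by 1.96 and Stx3 by 1.69. Mup20 (-2.88) and Mup6 (-2.46) belong to a family of near-identical copies, so which copy was measured is uncertain. Mup20, Mup6, Ppbp and Pla2g5 were well above background on 2 of the 4 hypoxia arrays, Plscr2 and Cldn2 on 1 and Ogn on 3. Calls were lost without pair 2 for Wnt4 (adjusted p = 0.0597) and Cldn2 (0.0565), without pair 3 for Mup20 (0.101), Mup6 (0.0792), Plscr2 (0.12), Pla2g5 (0.0832) and Akr1c14 (0.102), and without either for Ogn (0.0585 and 0.0579).

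S phase genes were lower in 27 of 29 members, with a median change of -0.33, although no single member passed in either fit, also when adjusted over the list alone. Tyms (-0.57, paired adjusted p = 0.0796) and Cdc6 (-0.63, paired adjusted p = 0.0806) had the smallest p. The list shifted down (camera adjusted p = 2.62e-06, and adjusted p = 0.722 with an estimated correlation), but 6 of the 35 splits gave as small a p, and the median in pair 4 was -0.00043. G2/M genes had a median change of -0.07 and did not pass as a list (adjusted p = 0.265). The values of their leading members were -0.38 for Ndc80 and 0.34 for Ccnb2.

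**Figure D2:**
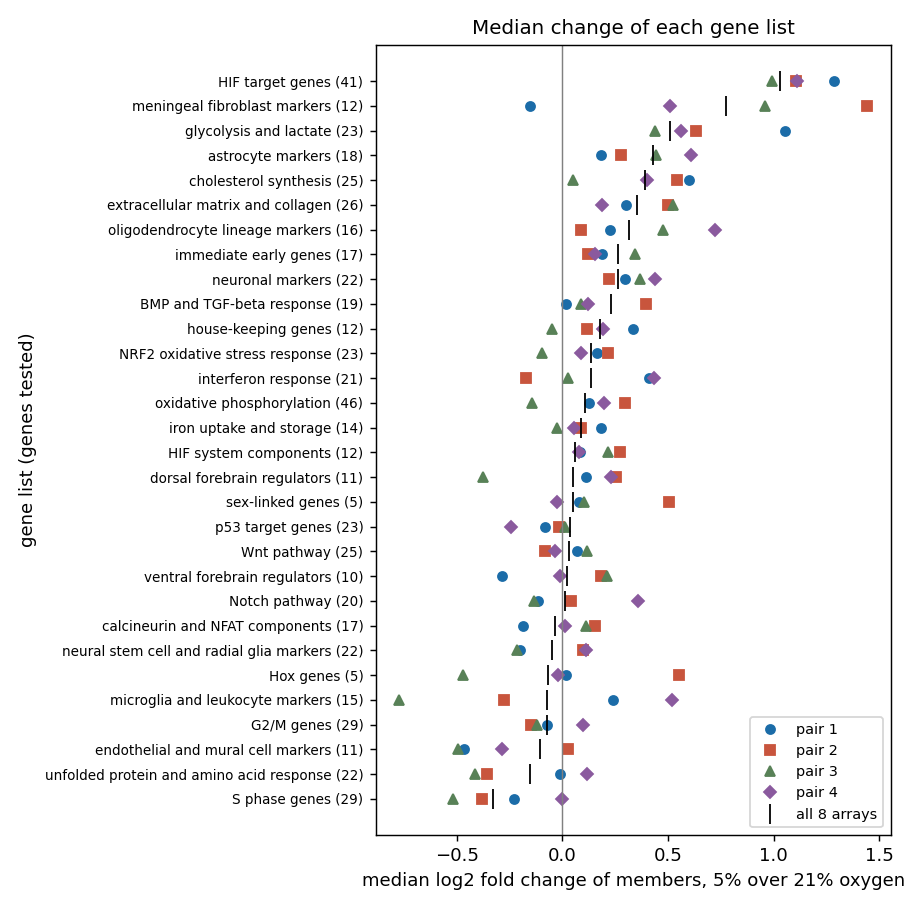
Median log2 fold change of hypoxia over normoxia over the members of each of the 30 gene lists tested, with the number of genes tested in brackets. Symbols are the 4 pairs and black bars the value over all 8 arrays; the HIF target median was 1.03 and the S phase median -0.33.

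Markers of differentiated neural cells shifted up as lists, and single members passed in the paired fit alone. Among 22 neuronal markers 4 rose, with the neurofilament gene Nefl at 2.87-fold, the tau gene Mapt at 2.38-fold, Gad2 at 1.74-fold and Nefm at 1.68-fold (camera adjusted p = 0.0118, and adjusted p = 0.261 with an estimated correlation). Among 18 astrocyte markers 4 rose, among them Ntsr2 at 2.19-fold, the glutamate transporter gene Slc1a2 at 1.89-fold and Fgfr3 at 1.79-fold (adjusted p = 0.0156 by camera, and adjusted p = 0.297 with an estimated correlation). Among 16 oligodendrocyte lineage markers Mbp rose by 2.94-fold and Cspg4 by 1.86-fold, while Mobp fell (adjusted p = 0.0118 by camera, and adjusted p = 0.499 with an estimated correlation). Adjusted over the list alone, the unpaired fit gave 1 rising neuronal marker and the paired fit 9 rising and 1 falling neuronal, 6 rising astrocyte and 5 rising and 1 falling oligodendrocyte markers. As small a p arose in 4, 8 and 9 of the 35 splits for the 3 lists in this order, and all 3 calls were lost without replicate 3. The neuronal call was also lost without hypoxia replicate 4 (adjusted p up to 0.0744 over all settings), the astrocyte call without normoxia replicate 1 or hypoxia replicate 3 (up to 0.149), and the oligodendrocyte call without hypoxia replicate 3, normoxia replicate 4 or replicate 4 and with no filter on dim probes (up to 0.29). Of 22 neural stem cell and radial glia markers only Fut4 rose (1.70-fold, paired fit), or 2 when adjusted over the list alone, and the list did not pass (adjusted p = 0.703). Among the members named here, Gad2, Nefm, Slc1a2 and Fut4 lost their calls without pair 1, 2 or 3, and Cspg4 without pair 1, 3 or 4. Nefl lost its call without pair 2 or 3, Fgfr3 without pair 1 or 3 and Mbp without pair 3. In these fits the paired adjusted p ran from 0.0553 to 0.182. The calls of Mapt, Ntsr2 and Mobp stood without any 1 pair.

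Markers of other cell types moved in both directions. Among 11 endothelial and mural markers the paired fit had 4 falling, among them Cldn5, Tek (-1.38, with 1 of the 4 hypoxia arrays well above background) and Acta2 (-1.28, lost without pair 3 at an adjusted p of 0.0571), and 2 rising, among them Pdgfrb (1.54), with the same counts adjusted over the list alone (unpaired 3 falling and 1 rising), and the list did not pass (adjusted p = 0.325). Among 12 meningeal fibroblast markers 4 rose in the paired fit, led by the collagen genes Col1a2 (1.83) and Col3a1 (1.40) and by Dcn (1.24), and 2 fell, Ogn among them. Adjusted over the list alone, 6 rose and 3 fell, and in the unpaired fit 1 rose. That list passed in the paired fit and not in the unpaired fit (adjusted p = 0.0469 and 0.211, and adjusted p = 0.80 with an estimated correlation in the paired fit). Over 42 settings with and without the block it passed in 18, and with the block it was lost by duplicateCorrelation (adjusted p = 0.131), under cyclic loess (0.0578), without pair 2 (0.164), without pair 3 (0.266) and with ranks (0.0848). Like Acta2, Cldn5 and Ogn, the single genes Tek (paired adjusted p = 0.0507), Col3a1 (0.0526) and Dcn (0.117) lost their calls without pair 3. Dcn also lost its call without pair 2 (0.0738). The calls of Col1a2 and Pdgfrb stood without any 1 pair. None of 15 microglia and leukocyte markers passed, nor did the list (adjusted p = 0.703) except with a direction of down without normoxia replicate 1 (0.0135), without hypoxia replicate 4 (0.0151) and in the leave-one-out with replicate block, without pair 4 (0.0414), with P2ry12 at -0.30 and Csf1r at -0.24. Of 11 erythroid genes on the array, the 4 that passed the filter on dim probes were too few for a list test. Klf1 (0.43) and Hbb-bh1 (0.30) did not pass, while adjusted over the list alone 1 rose in the paired fit.

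Extracellular matrix and collagen genes had a median change of 0.36 and were higher in 21 of 26 members, of which Col6a2 rose (1.74-fold, paired fit), or 6 in the paired fit when adjusted over the list alone. The Col6a2 call was lost without pair 1 (paired adjusted p = 0.0741) or 3 (0.061). The list shifted up (camera adjusted p = 0.00138, and adjusted p = 0.366 with an estimated correlation), 9 of the 35 splits gave as small a p, and the call was lost without normoxia replicate 1 and without replicate 3 (adjusted p up to 0.0833 over all settings). Among 17 immediate early genes Ier3 rose by 3.75-fold and Egr2 by 2.56-fold in the paired fit, and adjusted over the list alone 3 rose in the paired and 2 in the unpaired fit (camera adjusted p = 0.0378 for the list, and adjusted p = 0.297 with an estimated correlation). For that list 8 of the 35 splits gave as small a p, and the call was lost without any of 3 single arrays, normoxia replicate 1, hypoxia replicate 3 and hypoxia replicate 4, without replicate 1 or 3 and with no filter on dim probes (adjusted p up to 0.29 over all settings), and with ranks (0.114, and 0.0801 in the paired fit).

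By camera with the preset correlation no signalling list passed against other genes in the unpaired fit or the paired fit, but single members passed in the paired fit. Over the 42 settings of the test the unfolded protein and amino acid response list passed with a direction of down in 13 (smallest adjusted p = 0.00199, paired fit 0.0592, and 0.0464 there with ranks), the BMP and TGF-beta response list with a direction of up in 2 (smallest 0.0286) and the p53 target list with a direction of down in 1 (0.0487). In the Notch pathway the ligand gene Jag2 rose by 4.21-fold and Hey2, well above background on 3 of the 4 normoxia arrays, by 2.61-fold (list adjusted p = 0.777). In the Wnt pathway Sp5 rose by 2.28-fold and Dkk3 by 2.17-fold, and Wnt5a fell by 0.78 on the log2 scale (list adjusted p = 0.836). Among BMP and TGF-beta response genes 4 rose, among them Smad7 by 2.53-fold and Tgfbi by 2.07-fold, and Id4 fell by 1.06 (list adjusted p = 0.338). In the unfolded protein and amino acid response Cth fell by 1.35 and Sesn2 by 0.89, and Vldlr rose by 2.14-fold (list adjusted p = 0.104). Of the p53 targets Sesn2 and Ddit4l (-0.58) fell (list adjusted p = 0.325, with a median of 0.04, a mean of -0.05 and a test direction of down). Gsx2, a ventral forebrain regulator, rose by 2.43-fold (list adjusted p = 0.88). The Ddit4l call was lost without any 1 of the 4 pairs, and the Sp5, Tgfbi and Sesn2 calls without pair 1, 2 or 3. Wnt5a lost its call without pair 1, 3 or 4, Smad7 without pair 2 or 3, Id4 without pair 1 or 3 and Hey2 without pair 3. In these fits the paired adjusted p ran from 0.0508 to 0.229. The calls of Jag2, Dkk3, Cth, Vldlr and Gsx2 stood without any 1 pair. Adjusted over the list alone, the paired fit gave 3 rising and 2 falling Notch genes, 4 and 4 Wnt genes, 5 and 1 BMP and TGF-beta genes, 2 and 2 unfolded protein response genes, no rising and 2 falling p53 targets and 1 rising ventral regulator. In the unpaired fit it gave 1 rising Notch, 1 rising Wnt and 1 rising ventral gene. By fry for change in either direction, which sets no list against other genes, 24 of the 30 lists passed in the paired fit and 6 in the unpaired fit. In the paired fit they included the Wnt (adjusted p = 4.25e-05), Notch (0.000538), BMP and TGF-beta (0.0218) and housekeeping lists (0.0465), and none of these 4 passed in the unpaired fit.

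Of 17 calcineurin and NFAT components, Nfatc4 and Rcan2 rose by 2.12-fold each in the paired fit (paired adjusted p = 0.017 and 0.0143), and neither passed in the unpaired fit (0.0853 and 0.204). The Nfatc4 call was lost without pair 3 (paired adjusted p = 0.101) and the Rcan2 call without pair 2 (0.0627) or 3 (0.0848). This list was chosen with knowledge of published work on these samples, so its counts, including the 3 rising in the paired fit and the 2 in the unpaired fit when adjusted over the list alone, are not independent evidence. The other transcription factor genes did not pass, with changes of -0.43 for Nfatc1, 0.61 for Nfatc2, -0.19 for Nfatc3 and 0.04 for Nfat5. Nor did the calcineurin subunit genes Ppp3ca (-0.03), Ppp3cb (-0.04), Ppp3cc (0.08), Ppp3r1 (-0.24) and Ppp3r2 (0.03), or Rcan1 (-0.30) and Rcan3 (-0.23). The list did not pass (camera adjusted p = 0.955), and its median of -0.03 and its mean of 0.07 differed in sign, with a test direction of down. It passed by fry for change in either direction (adjusted p = 0.0131, and 0.00973 in the paired fit).

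No member passed in either fit, also when adjusted over the list alone except for 1 rising dorsal regulator in the paired fit, for the lists on the NRF2 oxidative stress response (list adjusted p = 0.498), interferon response (0.325), iron uptake and storage (0.917), dorsal forebrain regulators (0.777) and Hox genes (0.553). Of 22 Hox genes on the array only 5 passed the filter on dim probes and were tested. The interferon list passed with a direction of up without normoxia replicate 2 (adjusted p = 0.00347), without replicate 2 (0.00138) and in the leave-one-out with replicate block, without pair 2 (0.00275). Their members with the smallest p included Me1 (0.46), Xaf1 (0.79), Trf (0.48, in the iron list, whose median of 0.09 went against the downward direction of its unpaired test), Lef1 (0.72) and Hoxa9 (-0.26). Housekeeping genes did not pass by camera (list adjusted p = 0.521), with Tbp at -0.00, Sdha at 0.04 and Actb at 0.27. Sex-linked genes did not pass either (list adjusted p = 0.703), with Xist at 0.28 and Ddx3y at 0.05.

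The response to low oxygen was shared between the experiments in part. Across genes, the hypoxia minus normoxia differences of the 4 pairs correlated at 0.29 to 0.52 over the 6 combinations of pairs, with a median of 0.44. Genes are not independent replicates, so no test was made. The median fell to 0.24 with no filter on dim probes.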

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

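Of 362 groups of 4 values examined, 18 (4.97%) held 1 array far from the other 3 of its group, and chance gives about 1 in 20. Of these 18, 17 are given here. On hypoxia replicate 1 the housekeeping genes averaged 4.50 against 3.90 to 4.00 on the other hypoxia arrays, Ppia lay at 6.81, Cox8a at 7.21 and the erythroid list at -4.48, all above the other hypoxia arrays, and Hif1a lay below them at 1.21. Normoxia replicate 1, of the same pair, lay the same way in its own group for Cox8a (6.81 against 5.57 to 5.87), Ppia (6.30 against 5.22 to 5.51) and Hif1a (2.04 against 2.45 to 2.70). On hypoxia replicate 4 the endothelial and mural list averaged -2.16 against -2.94 to -2.85, Eno2 was low at 1.93 and Ndc80 high at 1.67. Calca was low on hypoxia replicate 3 at -1.28. Among normoxia arrays, replicate 1 was low for Loxl2 (-2.28) and Hey2 (-6.45) and high for Crebbp (2.40). Replicate 2 was high for Slc38a4 (-3.93), Mbp (-0.97) and Dkk3 (-1.26) and low for Nfatc4 (-4.33), and replicate 4 was high for Nfatc2 (-0.74). No explanation was tested for these values.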

How the results depend on the processing

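The paired fits with other scalings, with all-array detection, with other gene summaries and with flags ignored were chosen after seeing the data. The count of genes depended on the pairing: 24 without the block became 1482 with the replicate block, 1529 with the block by duplicateCorrelation, 1607 with normexp and quantile normalization, 450 with no filter on dim probes, 2294 with trend and robust moderation and 1474 on the authors' deposited value table, each with the block. Without the block it was 37 with normexp and 75th percentile scaling, 0 under quantile normalization, 0 under median scaling, 0 with no filter on dim probes, 11 under cyclic loess, 50 for probes above background on all 8 arrays, 37 for every probe on its own, 93 with trend and robust moderation and 114 with array weights. The unpaired fits that gave 0 had up to 2453 genes at an unadjusted p under 0.05 in limma. Leaving out arrays or pairs gave 0 to 58 genes without the block and 389 to 1429 with it, so the 1482 ranged from 389 to 1429. The cause was not tested, except that no filter meant 37074 genes tested and leaving out meant fewer arrays. Of the paired calls, 1247 recurred under quantile normalization, 1297 under median scaling and 1233 under cyclic loess. The share of rising genes among paired calls ran from 70.3% to 84.7%. The 9 lists became 0 with an estimated correlation and 2 by fry in 1 direction, 10 with the block, and 4 to 12 when arrays or pairs were left out (4 without replicate 3, 5 without pair 3 with the block). The HIF target, glycolysis, cholesterol and S phase lists passed under all 42 settings of the preset-correlation test, and with the block the meningeal fibroblast list was the 1 list whose call changed. The median correlation between pairs was 0.24 with no filter on dim probes. Among 147 named genes, 19, 22, 41 and 6 lost their paired call without pairs 1, 2, 3 and 4, and no called gene changed direction. Signal over background limits the dim genes.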

Other observations

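Tests chosen after the result was seen were those of scaling on the share of rising genes, of G2/M against S phase medians, of other cell types against neural markers (by medians, and then by a count after the medians had left it open) and of scaling on parts of the neural lists, and the lists of NF-kB targets and imprinted genes were written after the rising genes were seen. Several genes outside the lists above rose in the paired fit. Among NF-kB targets, Bcl3 rose by 2.52 (log2, SE 0.15), Cd40 by 2.12, Ptgs2 by 2.07, Tnfaip3 by 1.99 and the chemokine gene Cxcl1 by 1.90, while Ccl2 fell by 0.66. Ptgs2 was well above background on 1 of the 4 normoxia arrays and Cxcl1 on 2. The hypothesis that NF-kB targets rise as a group was tested on the 20 members whose change had not been seen. Of these, Cxcl1 and Tnfaip2 (0.66) rose in the paired fit and Ccl2 fell. The shift of the 20 did not pass (limma camera, adjusted p = 0.997 over 2 lists), although that of all 27 members did (adjusted p = 0.00162). The shift of the whole list therefore rests mainly on genes noticed first. The 7 members left out had been noticed among the rising genes. Leaving them out favours a failed test, which therefore does not settle whether the group rose.

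Imprinted genes, expressed from 1 parental copy, also held rising members in the paired fit. H19 rose by 2.80 (SE 0.34), Meg3 by 1.78, Ascl2 by 1.55, the cell cycle inhibitor gene Cdkn1c by 1.19 and Grb10 by 0.60, and Peg12 fell by 0.69. The hypothesis that imprinted genes rise as a group was not borne out on the 24 members whose change had not been seen (limma camera, adjusted p = 0.644 over 2 lists). The shift of all 26 members did not pass either (adjusted p = 0.0519). The 2 members left out had been noticed among the rising genes, so this test has the same limit.

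For the count of 24 genes, 1 of the 35 splits of the 8 arrays, the real one, gave as many, and the highest other count was 19, a share under 0.05 that excludes chance only if the pairing is left aside. Among the 8 splits that part all 4 pairs, which keep to the pairing, the real one gave 24 and the others 0, and 8 splits are too few for a share under 0.05. The splits with 19, 11 and 3 genes were those that set whole pairs against each other, which points to differences between the experiments. For the paired count of 1482, 1 of the 8 such splits, the real one, gave as many and the highest other was 0, with the same limit. For the count of 9 lists, 15 of the 35 splits gave as many and the highest other was 12, so chance cannot be excluded for that count. List by list, the number of permutations of the arrays, out of 35 splits, with as small a camera p was 1 for HIF targets (smallest other p = 2.98e-20) and 1 for glycolysis (9.32e-11), which excludes chance only if the pairing is left aside. Both of these other values came from splits that part all 4 pairs, of which there are too few for a share under 0.05. It was 2 for cholesterol synthesis (3.84e-12), 6 for S phase (9.75e-10), 9 for extracellular matrix (1.58e-14), 4 for neuronal (8.11e-05), 8 for astrocyte (0.00026), 9 for oligodendrocyte (6.04e-07) and 8 for immediate early genes (3.93e-06), for which it cannot.

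More genes rose than fell in the paired fit. Scaling to the 75th percentile as the whole cause is argued against by a share of rising genes of at least 70.43% under quantile, median and cyclic loess scaling. Signal near background is argued against by a share of 75.53% among genes above background on all 8 arrays. Low oxygen itself may account for the excess, a hypothesis that arose from these data and was not tested.

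S phase genes were lower as a list while G2/M genes did not pass. Scaling that lowers bright genes is argued against, since 0% of 10000 random lists of like signal had a median as low as -0.33. A smaller share of dividing cells stays open. The G2/M median lay above 50% of the S phase median in 4 of 4 pairs, but by more than 2 standard errors in 2. That margin was set after the values were seen. The pair medians still held each pair's median difference over all genes (0.02, 0.16, -0.13 and 0.05), on which the count of pairs depends. Differences between arrays unrelated to oxygen may also produce such a shift, as 6 of the 35 splits gave as small a p.

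Neuronal, astrocyte and oligodendrocyte lists were higher. Scaling to the 75th percentile moves all genes of an array alike, so it cannot by itself raise a list's mean change above that of other genes. Median scaling does the same, and left that mean change at 0.34, 0.36 and 0.42 for the 3 lists in the paired fit. All 3 lists kept their calls under 1 of 3 scalings, by the median, which tests nothing here. The neuronal and astrocyte lists kept 4 of 4 paired calls under quantile and cyclic loess scaling. For these 2 lists this argues against a scaling effect that differs with signal. The oligodendrocyte call, near the threshold in the paired fit (adjusted p = 0.0469), ended in the replicate block with quantile normalization (0.0563) and the replicate block with cyclic loess normalization (0.0536), although its unpaired call stood under both. Its mean change above all other genes was 0.42 (SE over members 0.23) before and 0.42 (0.24) and 0.43 (0.24) after, so the call did not end for a smaller shift. An unchanged shift argues against a scaling effect that differs with signal for this list too. The shift lay within 2 standard errors over members, short of the margin set for the test, so the rise itself stays uncertain. A smaller share of stem cells, with every other cell type larger, stays open, since single markers do not measure the share of a cell type. Markers of the same cell type moved both ways: Pdgfrb rose while Acta2 fell, and Col1a2 rose while Foxc1 fell. Of 27 markers of other types above background on all 8 arrays 6 rose and 3 fell. The falls were 2.36 for Cldn5 (SE 0.31), 1.28 for Acta2 (0.21) and 0.96 for Foxc1 (0.17). As many fell in 0.95% of 10000 random lists of like signal and as many rose in 0.21%, shares with limits: such lists ignore correlation between markers, the count was chosen with some of these falls known, the Cldn5 and Acta2 calls ended without pair 3 (-2.04, SE 0.31, adjusted p = 0.0519, and -1.03, SE 0.16, 0.0571), and the medians of microglial and endothelial members parted from the neural lists by more than 2 standard errors in 1 of 4 pairs. A change in the neural types themselves stays open, as does differentiation at low oxygen, which may be a biological explanation and was not tested, and the test without members on the HIF and glycolysis lists took none out, so all 3 calls stood and nothing was decided.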
